A study of Homo sapiens with 3 samples.

How the data were processed

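RNA abundance was measured in human mesenchymal stem cells, adherent multipotent stromal cells that can be driven to bone, fat or cartilage fates, with 3 Affymetrix oligonucleotide arrays. The arrays were 1 of untreated cells, 1 of cells given recombinant Wnt3a at 100 ng/ml for 6 h, and 1 of cells given it for 24 h. Wnt3a is a secreted ligand that stabilises beta-catenin. Cells were grown in DMEM with serum in culture dishes, total RNA was taken with a Qiagen kit and the target was labelled with biotin by the manufacturer's standard procedure, per the labels' protocols. When the untreated cells were collected is not given in the sources used here, so any change against control can include time in culture or a medium change. The origin of the cells and the number of cultures are not given either.

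The deposited values are linear array intensity, 1 value per probe set, and the authors used GCOS, Affymetrix's operating software, per the submitters' processing notes. Its version, its algorithm settings and the target intensity for scaling are not given in the sources used here. The table held 54675 probe sets, of which 62 were the manufacturer's controls. The arrays were not on an equal scale as deposited. The median signal was 30.8 on the control array, 27.4 on the 6 h array and 26.6 on the 24 h array, and the 75th percentiles were 192, 177 and 162. The mean without the lowest and highest 2% of probe sets was 222, 213 and 195. The 3' to 5' signal ratio of GAPDH was 0.900, 0.915 and 0.937 on the control, 6 h and 24 h arrays, and that of ACTB was 1.18, 1.17 and 1.11. Over all probe sets, the log2 signals of the 6 h and control arrays correlated at r = 0.969, those of the 24 h and control arrays at 0.960 and those of the 24 h and 6 h arrays at 0.965. These coefficients run across probe sets, which are not independent replicates.

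Signals were used as deposited. A pseudocount of 7.63, the 25th percentile of all values, was added before taking log2, which reduces the change of dim genes. Probe sets whose mean over the 3 arrays lay below the median probe set, a signal of 25.9, were left out. Of the probe sets, 42898 were in the platform annotation used here, 41097 of them with 1 gene and 1801 with several, and 11777 were not listed in it and stayed unnamed. Gene symbols of 41043 probe sets were matched to RefSeq by gene identifier, and 54 kept the annotation's symbol. A gene was represented by its brightest remaining probe set naming that gene alone, which gave 12306 measured genes, 6248 of them with at least 2 probe sets. XIST and Y-linked genes were left out.

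The comparisons were 6 h against control, 24 h against control and 24 h against 6 h. With 1 array per group there are no replicates, so no test, p-value or standard deviation across samples could be given, and the number of arrays limits the precision of each value. A gene was called higher or lower at a change of at least 2-fold, a log2 change of 1 on the pseudocount scale. A probe set pair of the same gene checks the probe sets and not the biology, since both lie on the same array. The median gene changed by -0.09 log2 at 6 h, -0.22 at 24 h and -0.13 between 24 h and 6 h, so medians of gene lists are given relative to that gene. Single-gene changes and counts are on the deposited scale. A list's relative median is set beside its percentile among 10000 random lists of the same size matched on mean signal, as a description of these arrays. No percentile was taken for a list with fewer than 3 measured genes.

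The comparisons, 27 gene lists, the rule for naming genes and 8 alternative settings were fixed before the data were examined. The rule took 3 kinds of gene. The first were the 10 largest rises and 10 largest falls against control, and the 5 largest of each between the treated arrays. They came from genes with at least 2 probe sets, a 2-fold change and all probe sets moved the same way by at least 0.5 log2. The second were list members with a 2-fold change, and the third a set of Wnt targets and lineage markers named whatever their change. The alternatives were a pseudocount of 1 or of the median value, no filter, a filter keeping the top 30% of probe sets, quantile normalization, division by the 75th percentile, the mean over a gene's probe sets, and the omission of probe sets that can match several transcripts. Scaling on the 18 hybridization control probe sets, and 3 further gene lists, were chosen after seeing the data. The calculations for 6 h and 24 h against control were tested on simulated arrays with 200 changed genes and a noise SD of 0.25 log2. At 6 h, 96% of genes raised by 1.5 log2 and 78% of those lowered by 1.5 were recovered, and at 24 h 84% and 78%. Of genes changed by 3 log2, 100% of raised and 70% of lowered ones were recovered at either time. The lowered genes of that size that were missed had dropped below the filter on the mean of the arrays. Of 12118 unchanged genes, 0.32% were called at 6 h and 0.34% at 24 h. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Scanner images, probe-level files and detection calls were not used here.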

Results

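The series measured how the transcriptome of human mesenchymal stem cells differed from that of untreated cells after 6 h and 24 h with recombinant Wnt3a. There was 1 array per group, so each change below compares 2 arrays and has no replicate error, and the design holds no untreated cells matched to 6 h or 24 h. Signals are linear array intensities as deposited, and changes are log2 of treated over control on the pseudocount scale.

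After 6 h, AXIN2 and DKK1, feedback inhibitors of Wnt signalling that are direct beta-catenin targets, were higher than in untreated cells. The AXIN2 signal was 147 in control and 1476 at 6 h, a log2 change of 3.27, and its 4 probe sets ranged from 1.54 to 3.27. The DKK1 signal went from 598 to 3406. The neutrophil chemokine CXCL8 had the largest rise by the naming rule, from 28.2 to 799, or 4.49. PTGFR, the prostaglandin F receptor, and FGF7, a fibroblast-derived growth factor for epithelia, fell by 2.15 and 1.84. Of 12306 measured genes, 244 were at least 2-fold higher and 289 at least 2-fold lower at 6 h, 4.33% together.

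The direction of that split depends on scaling and on the filter. With the filter keeping the top 30% of probe sets, the split was 142 higher and 99 lower. It was 323 higher and 186 lower with quantile normalization and 321 and 203 with each array divided by its 75th percentile. It was 291 and 220 with scaling on the hybridization controls, an alternative chosen after seeing the data. Of genes with a second probe set, that probe set lay on the same side for 88 of 93 higher and 83 of 99 lower genes, where chance gives 50%.

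Among genes with at least 2 probe sets that moved together, the 10 largest rises at 6 h also included TSPAN2, a tetraspanin (3.61), E2F7, a repressor of the E2F family (3.19), EDN1, the endothelin-1 precursor (2.91), and KRTAP1-3, a hair keratin-associated protein (2.84). ELN, which encodes elastin, changed by 2.46 and HAS2, a hyaluronan synthase, by 2.41, from 695 to 3726. These sizes are the brightest probe set's: another probe set gave 0.87 for E2F7, 0.77 for EDN1 and 0.97 for ELN, but 2.83 for HAS2. FAM124A and the ephrin receptor EPHB1 both changed by 2.27, from dim control signals of 14.2 and 17.9. Among the same kind of gene, the 10 largest falls also included FIBIN (-1.86), SPRY1, an inhibitor of receptor tyrosine kinase signalling (-1.75), SLC25A27 (-1.72), SERTAD4 (-1.70), the iron exporter SLC40A1 (-1.67), PLD1 (-1.58), ASAP3 (-1.57) and ZSCAN12 (-1.51).

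Of 13 measured Wnt target and feedback genes, 3 rose at 6 h (AXIN2, DKK1 and the receptor FZD7, at 1.31), 10 changed by less than 2-fold and none fell, and 5 rose with division by the 75th percentile. The list's relative median was 0.64, at percentile 100 of random lists. LEF1, a nuclear partner of beta-catenin, changed by 0.97, ZNRF3 by 0.89, NOTUM by 0.55, CCND1 by 0.45 and MYC by 0.42. A second CCND1 probe set gave 1.09. NKD1, RNF43, SP5, LGR5 and APCDD1 lay below the signal filter, and no probe set named TCF7 alone. Of 21 Wnt ligands, receptors and secreted modulators, 2 rose, DKK2 at 1.01 and WNT5B at 1.09, and 1 fell, FZD5 at -1.65, with a relative median of 0.05 (percentile 68.3). Of 21 components of the destruction complex and TCF cofactors, 2 rose, the corepressor TLE1 (1.52) and the scaffold AXIN1 (1.11), with a relative median of 0.04 (percentile 71.5) that turned to -0.0701 with the stricter filter, where 1 of 15 rose.

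Several signalling lists were higher at 6 h. Of 16 NF-kappaB and inflammatory cytokine genes 9 rose and 1 fell, with a relative median of 1.35 (percentile 100). Among the risers were CXCL8, LIF (2.94), CXCL6 (2.72) and CXCL1 (2.20), and also NFKBIA (1.83) and TNFAIP3 (1.89), which restrain NF-kappaB. The 1 that fell was IL6, at -1.38. Of 11 BMP response genes and antagonists 5 rose and none fell (relative median 0.94, percentile 100). ID1, a BMP-induced inhibitor of helix-loop-helix factors, changed by 2.17, BAMBI by 1.66 and SMAD9 by 1.65. Of 10 TGF-beta response genes 5 rose (relative median 0.90, percentile 100), among them COL4A1 (2.07), TGFB2 (1.51) and TGFBI (1.37), and 3 did with the mean over probe sets. Of 14 immediate early genes 5 rose (relative median 0.77, percentile 100), including FOS (2.45), IER3 (2.10) and DUSP1 (1.56). Of 6 Notch response genes 1 rose, HEY2 at 2.03 (relative median 0.35, percentile 97.3). Of 8 YAP/TAZ response genes 1 rose, F3, with a relative median of 0.17 (percentile 87.8).

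Lower lists at 6 h held few genes past 2-fold. Of 14 amino acid and ER stress genes 2 fell, DDIT4 at -1.63 and TRIB3 at -1.43 (relative median -0.62, percentile 0.0). In the interferon response list 1 of 13 fell, IFIT1 at -1.54 (relative median -0.49, percentile 0.01), and in the p53 response list 1 of 9, GDF15 at -1.66 (relative median -0.33, percentile 0.08).

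Among lineage genes at 6 h, 3 of 13 osteoblast genes rose and 2 fell, with a relative median of 0.11 (percentile 82.2) that turned to -0.24 without multi-transcript probe sets and to -0.0052 with quantile normalization. BMP2, an osteogenic ligand, changed by 1.59, DLX5 by 1.45 and BMP6 by 1.40, against -1.33 for TNFRSF11B, the decoy receptor osteoprotegerin, and -1.16 for OMD. RUNX2, the master factor of osteoblasts, changed by -0.65, with probe sets from -0.81 to 0.23, and ALPL by 0.47. Of 16 adipocyte genes 1 rose, ZNF423 at 1.07, and 2 fell, KLF15 at -1.84 and G0S2 at -1.47 (relative median -0.34, percentile 0.01). PPARG, the master factor of fat cells, changed by -0.63. None of 10 chondrocyte genes passed 2-fold (relative median -0.10, percentile 22.6, but 0.30 with the stricter filter), though 1 did with each of the other scalings, and none of 14 stromal cell surface and niche genes did (0.05, percentile 37.9). The surface markers NT5E, THY1 and ENG changed by -0.07, -0.05 and 0.31. Of 21 matrix genes 1 rose, ELN (relative median 0.25, percentile 99.95). Of 10 smooth muscle contractile genes 2 rose, ACTG2 at 1.77 and CNN1 at 1.18 (0.42, percentile 99.94).

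After 24 h, genes of DNA replication and mitosis were higher than in untreated cells, and genes of cholesterol synthesis and fat cells were lower. All 16 measured G2 and M phase genes rose, with a relative median of 2.16 (percentile 100). The mitotic kinase CDK1 went from 447 to 2598, a change of 2.52, UBE2C changed by 2.54 and TOP2A by 2.29. Of 15 S phase genes 12 rose and none fell, among them the cyclin CCNE2 at 3.18 (relative median 2.13, percentile 100). At 6 h none of the G2 and M phase genes had risen (relative median 0.09, percentile 87.5). Of the S phase genes 2 had risen at 6 h, CCNE2 and UHRF1, and 13 lay above the median gene (relative median 0.39, percentile 99.99). With quantile normalization, the 75th percentile or the hybridization controls, 5 S phase genes had risen at 6 h. For CCNB2, at 1.85, a second probe set gave -0.55, and GINS2 changed by 3.04 but by -0.0094 with multi-transcript probe sets left out.

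In all, 458 genes were at least 2-fold higher and 939 at least 2-fold lower at 24 h, 11.4% of those measured. The majority turns with scaling: the split was 651 higher and 554 lower with quantile normalization, 674 and 522 with the 75th percentile, and 690 and 496 on the hybridization controls. The second probe set lay on the same side for 173 of 183 higher and 363 of 407 lower genes.

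**Figure D1:**
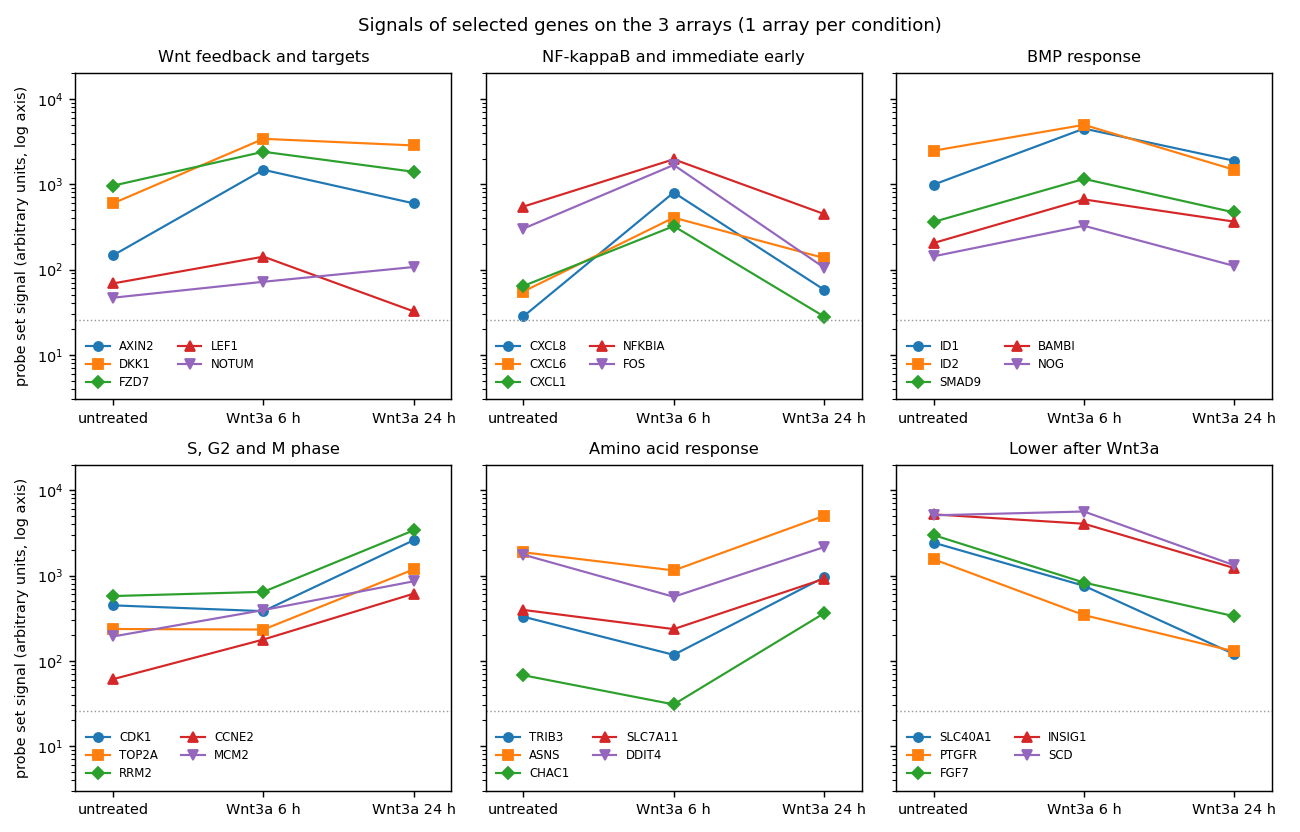
Array signals (linear intensity, log axis) of named genes on the control, 6 h and 24 h arrays, 1 array each, so no error bars are drawn, with the filter level of 25.9 as a dotted line. AXIN2 went from 147 to 1476 and 596, and CDK1 from 447 to 382 and 2598.

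Among genes with at least 2 probe sets that moved together, NRG1 led the rises at 24 h. NRG1, an ErbB receptor ligand, went from 41.1 to 688 (3.84), followed by TSPAN2 (3.81), E2F7 (3.72), RTKN2 (3.72, from a dim 10.3), EDN1 (3.47), KRTAP1-3 and CCNE2 (both 3.18), the replication licensing factor CDT1 (2.94), MICAL2 (2.79) and DTL (2.77). The largest falls among such genes were in SLC40A1, from 2426 to 119.5 (-4.26), DAPK2 (-3.96), the transcriptional coactivator EYA1 (-3.89), PTGFR (-3.51), the monoamine oxidase MAOA (-3.26), EMCN (-3.19), FGF7 (-3.13), STON2 (-3.01), the aggrecan-cleaving protease ADAMTS5 (-2.87) and MTSS1 (-2.79). Each size is that of the gene's brightest probe set, and other probe sets could be far smaller. The smallest 24 h changes were 0.79 for EDN1, 0.91 for CDT1 and -0.70 for MAOA, but 2.72 for TSPAN2 and 2.44 for DTL. The 24 h signals of DAPK2, MAOA and EMCN were below the filter level, so the size of their change depends on the pseudocount. The same holds for the 24 h signals of WNT7B and CTNNBIP1 and for the control signals of ACTG2, IL11, F3 and ALPL.

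At 24 h, 3 of 13 Wnt target and feedback genes rose and none fell (relative median 0.65, percentile 100). They were DKK1, at 2.24, AXIN2, at 1.97 with probe sets from 0.10 to 2.14, and NOTUM, at 1.08. FZD7 was at 0.54. LEF1 was at -0.94, ZNRF3 at 0.13, CCND1 at 0.64 and MYC at 0.62, and a second CCND1 probe set was at 1.41. Of the 13 genes, 8 lay above the median gene. With the mean over a gene's probe sets 4 rose and 1 fell. Of 21 Wnt ligands, receptors and modulators 2 rose and 5 fell (relative median -0.21, percentile 3.71, but 0.16 without multi-transcript probe sets). The Wnt antagonist DKK2 changed by 3.77, from 40.4 to 648, and WNT5B by 1.12, while WNT7B fell by 2.49, FZD5 by 2.02 and the antagonist SFRP1 by 1.31. With division by the 75th percentile that list had 4 higher and 2 lower of 20. Of the destruction complex and TCF cofactors 1 fell, CTNNBIP1 at -2.05 (relative median -0.05, percentile 36.1).

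Fat and cholesterol genes were lower at 24 h. Of 16 adipocyte genes 7 fell and none rose, with a relative median of -0.67 (percentile 0.0). FABP4, at 0.27, and ZNF423, at 0.56, were the 2 above the median gene, and 4 further members lay below the filter. SCD, a fatty acid desaturase, changed by -1.94, LEP by -1.90, G0S2 by -1.62 and CEBPD by -1.56, and PPARG by -0.78. Of 10 cholesterol synthesis genes 6 fell and none rose (relative median -0.90, percentile 0.0), against none past 2-fold at 6 h. INSIG1, a sterol-regulated brake on the pathway, went from 5211 to 1222, a change of -2.09, and HMGCS1, an early enzyme of it, changed by -1.67. Only 2 of the 10 passed 2-fold with division by the 75th percentile. Of 13 interferon response genes 6 fell (relative median -0.49, percentile 0.28), with IFIT1 at -2.19, MX1 at -1.58 and IFIT3 at -1.49, and 4 did with that scaling. Of 9 p53 response genes 3 fell (relative median -0.64, percentile 0.02), TP53INP1 at -1.26, ZMAT3 at -1.22 and CDKN1A, the p21 cell cycle inhibitor, at -1.04. Of these 1 passed 2-fold with that scaling and none did on the hybridization controls.

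For the lineage lists at 24 h, RUNX2 fell from 1023 to 330.5, a change of -1.61, with probe sets from -1.61 to -0.77. ALPL changed by 0.97. The osteoblast list had 1 higher, BMP6 at 1.11, and 2 lower of 13, or 2 higher and 1 lower with the other scalings (relative median 0.07, percentile 69.1). Of 10 chondrocyte genes, the cartilage matrix protein COMP rose by 2.58, from 439 to 2659.5, and ACAN, the aggrecan core protein, fell by 1.32 (relative median -0.37, percentile 2.31, but 0.20 with the stricter filter). Of 14 stromal surface and niche genes 3 fell, ANGPT1 at -2.60, KITLG at -1.68 and VCAM1 at -1.25 (relative median -0.26, percentile 0.64), with NT5E at 0.02, THY1 at -0.14 and ENG at -0.35. Of 21 matrix genes 3 rose, MMP3 at 1.54, ELN at 1.11 and COL5A1 at 1.08 (relative median 0.20, percentile 96.5). Of 10 smooth muscle genes, ACTG2 at 2.47 and CNN1 at 1.15 rose and LMOD1 fell at -1.39 (relative median 0.36, percentile 98.8).

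For the signalling and stress lists at 24 h, 4 of 10 TGF-beta response genes stood past 2-fold (relative median 0.62, percentile 99.98), with COL4A1 at 2.17, and 2 did with the mean over probe sets. None of 11 BMP genes did (0.15, percentile 80.3), but 2 did with quantile normalization, the 75th percentile or the hybridization controls. The NF-kappaB list had 3 higher and 4 lower (relative median 0.05, percentile 69.4), with LIF at 3.04 and IL11 at 2.93 against ICAM1 at -1.73 and SOD2 at -1.25. With division by the 75th percentile the split was 5 higher and 2 lower. The immediate early list had 1 higher, IER3 at 2.17, and 1 lower, FOS at -1.45 (relative median 0.35, percentile 99.3, but -0.06 without multi-transcript probe sets). In that list 3 rose with the 75th percentile and 4 on the hybridization controls. In the amino acid and ER stress list 4 of 14 rose, CHAC1 at 2.29, TRIB3 at 1.51, ASNS at 1.42 and SLC7A11 at 1.19 (relative median 0.39, percentile 99.83). HEY2 was the 1 of 6 Notch genes past 2-fold, at 1.60 (0.14, percentile 70.9), and F3 the 1 of 8 YAP/TAZ genes (0.49, percentile 99.6).

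Of 8 epithelial markers only KRT14, a basal keratin, passed the filter, with signals of 54.3, 108 and 1197 and changes of 0.91 and 4.28. Of 9 endothelial markers 3 were measured (relative medians 0.17 and 0.67, percentiles 77.3 and 96.2, the first -0.26 with the mean over probe sets), and EMCN fell at 24 h. Of 13 haematopoietic markers 7 were measured (relative medians -0.01 and -0.42, percentiles 54.5 and 4.70), and CD14 was at -1.01, short of 2-fold with the other scalings, and -1.84. None of 10 reference genes passed 2-fold at 6 h or 24 h (relative medians 0.11 and 0.14, percentiles 70.4 and 80.8).

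**Figure D2:**
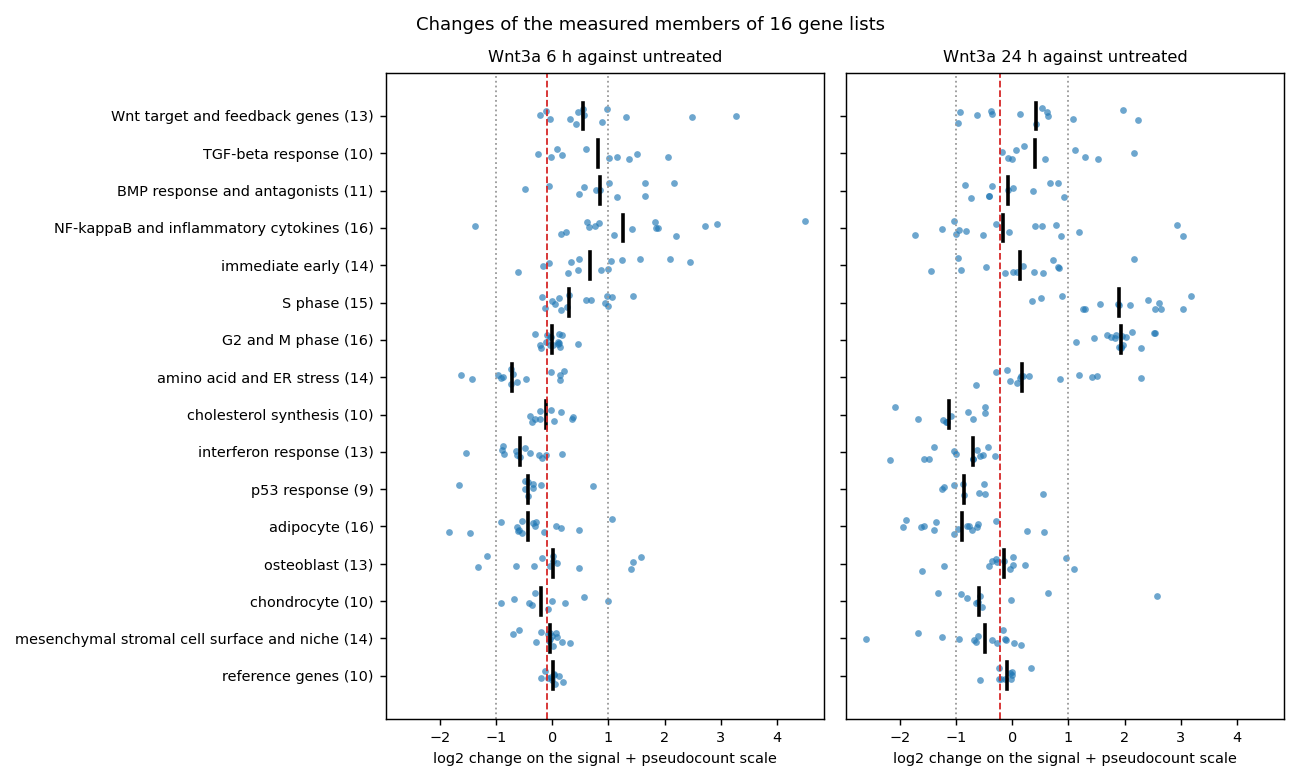
Log2 change of each measured member of the gene lists at 6 h and at 24 h against control, 1 array per group, with a black bar at each list's median, a dashed line at the median gene, dotted lines at 2-fold and the number of measured members in parentheses. All 16 G2 and M phase genes lie above 2-fold at 24 h and none does at 6 h.

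Between 6 h and 24 h, the medians of the cell cycle and amino acid stress lists rose while those of the cytokine and BMP lists fell. All 16 G2 and M phase genes and 11 of 15 S phase genes were at least 2-fold higher at 24 h than at 6 h. Of 14 amino acid and ER stress genes 7 were higher (relative median 1.07, percentile 100), among them TRIB3, a stress-induced pseudokinase, whose signals were 329 in control, 118 at 6 h and 952 at 24 h. Of 16 NF-kappaB genes 11 were lower and 1 higher (relative median -1.36, percentile 0.0), and of 11 BMP genes 5 were lower (-0.85, percentile 0.0). In the Wnt target list 2 of 13 were lower, LEF1 at -1.90 and AXIN2, whose signal was 596 at 24 h after 1476 at 6 h (relative median -0.28, percentile 0.805).

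Among genes with at least 2 probe sets that moved together, the largest rises over that interval were in TRIB3 (2.94), CDK1 (2.74), the mitochondrial folate enzyme MTHFD2 (2.69), HMMR (2.64) and DEPDC1 (2.56). The largest falls among them were in CXCL8 (-3.62), DAPK2 (-2.95), SNCAIP (-2.82), EYA1 (-2.76) and EMCN (-2.66). In all 347 genes were higher and 478 lower, 6.70% of those measured. The split was 420 and 359 with quantile normalization, 436 and 339 with the 75th percentile, and 486 and 288 on the hybridization controls. This comparison does not use the control array.

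Of the 244 genes higher at 6 h, 135 were still at least 2-fold above control at 24 h, such as TSPAN2, EDN1 and HAS2, and 51 had come down at least 2-fold from 6 h, such as CXCL8. These groups overlap, and AXIN2 was in both. Of the 289 genes lower at 6 h, 136 were still lower at 24 h, such as PTGFR and FGF7, and 52 had come back up by 2-fold. Independent lists of these sizes would share 9.08 higher and 22.1 lower genes. Arrays simulated as unchanged, with a noise SD of 0.208 log2 taken from the difference between probe sets of a gene, shared 0 higher and 1.79 (0 to 6) lower genes on average. This noise leaves out variation between cultures. It is also the same for dim and bright genes and small against a 2-fold change, so it could hardly give many shared genes. Arrays made by dealing each gene's 3 values to the arrays at random, which keeps the size of real changes in the values, shared 97.0 (70 to 117) higher and 199 (172 to 245) lower genes. Across genes, which are not independent replicates, the changes at 6 h and 24 h correlated at r = 0.577 with a covariance of 0.170. The noise simulation gave 0.501 and 0.0433, and the dealt values 0.501 and 0.151. Both comparisons use the 1 control array, so part or all of the excess over independent lists may come from it. Neither simulation can say how much, since the dealt values keep real changes and the noise leaves out variation between cultures. The 136 shared lower genes lay below the range of the dealt values, and the 135 shared higher genes above it. The genes that came back toward control were picked on the 6 h array and then compared with it. Noise on that array alone can therefore add to the 51 and 52 such genes.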

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

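The tests of array brightness and of the spread of its controls, of unfolded protein genes, of time in culture and of ATF4 targets at 6 h, the scaling on hybridization controls and the list of further ATF4 targets were chosen after the results were seen.

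Against control, 5 named genes moved at least 2-fold one way at 6 h and at least 2-fold the other way at 24 h. In 1 list the medians, each short of 2-fold, lay in opposite tails of random lists. These differences were not tested, because each rests on single arrays. Over all 12306 measured genes, 5 were higher and then lower, and 4 lower and then higher. Independent lists would give 18.6 and 10.8, and the dealt values gave 11.0 (2 to 18) and 7.49 (3 to 14). CXCL1, a neutrophil chemokine, changed by 2.20 and then -1.01, a difference of -3.21, and its 24 h value no longer passed 2-fold under the other scalings. FOS, a component of AP-1, changed by 2.45 and -1.45, a difference of -3.90. SNCAIP changed by 1.03 and -1.79, a difference of -2.82, but its other probe set was short of 2-fold at both times, at 0.80 and -0.75. MTHFD2 changed by -1.06 and 1.62, a difference of 2.69. Its 6 h value was short of 2-fold under some of the other scalings, and its other probe set gave -0.52 at 6 h. TRIB3 changed by -1.43 and 1.51, a difference of 2.94. The amino acid and ER stress list had relative medians of -0.62 and 0.39, and the median of its members' changes from 6 h to 24 h was 0.94 on the deposited scale.

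The amino acid and ER stress list was lower at 6 h, where DDIT4 and TRIB3 fell by more than 2-fold, and higher at 24 h, where CHAC1, TRIB3, ASNS and SLC7A11 rose. An unfolded protein response raising HSPA5, XBP1, HERPUD1 and DNAJB9 is argued against: their relative median between 6 h and 24 h was -0.153. The other 10 members had 1.96. These 4 genes do not read every branch of that response, so a branch acting through ATF4 stays open. For the rise from 6 h to 24 h, an ATF4 amino acid response may account for it: 19 further ATF4 targets had a relative median of 0.61 between these times, at percentile 100 of random lists, with 3 higher (SLC7A5, CEBPG and PCK2) and none lower. For the fall at 6 h it stays open, since these targets had a relative median of -0.05 against control, at percentile 7.20, with 1 higher (STC2) and none lower. Whether Wnt3a or time in culture and a medium change drove it cannot be told apart, because the design holds 1 untreated array of no stated time.

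More genes were 2-fold lower than higher at 24 h as deposited, 939 against 458. A dimmer 24 h array may account for this: the hybridization controls, added to each sample at a fixed amount after labelling, had a median change of -0.29 (17 of 18 lower, SD 0.142), close to the -0.22 of the median gene. Whether more transcripts fell than rose stays open. With arrays scaled on those controls the ratio of lower to higher genes was 0.719, under the bound of 1 set for that ratio. That scaling was itself chosen after the results were seen. It also moves every gene on an array alike, and the ratio follows the size of that shift. Shifting by each of the 4 control transcripts gave ratios from 0.514 to 1.05. The poly-A controls, added to the RNA before labelling, were lower on 24 of 24 probe sets (median change -0.50) and their mean gave 0.212.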

How the results depend on the processing

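Scaling on the hybridization controls was the 1 setting chosen after the results were seen. No paired analysis was possible because each group had 1 array. Over 9 settings, 435 of 468 list medians moved by no more than the standard error over the list's genes, and 2683 of 2778 changes of named genes by no more than the spread between probe sets of a gene. These tallies are a weak check, because part of them could hardly fail. Changing the filter leaves the brightest probe set of a kept gene as it is. Scaling moves the genes of an array nearly alike, and medians relative to the median gene mostly cancel such a shift. The numbers of genes past 2-fold moved by over 1.5 times as follows. With the median value as pseudocount, 307 genes changed at 6 h (153 higher, 154 lower), 608 were lower at 24 h and 310 were lower between 6 h and 24 h. Without a filter, which adds dim genes, the totals were 1913 at 6 h (893 higher, 1020 lower), 2864 at 24 h (1122 and 1742) and 2250 between the times (1038 and 1212). With the stricter filter, which leaves fewer genes, they were 241 (142 and 99), 793 (278 and 515) and 463 (188 and 275). Scaling removed falls: at 6 h 186 genes were lower with quantile normalization, and at 24 h 554 with it, 522 with the 75th percentile and 496 on the hybridization controls, where 690 were higher and, between the times, 288 lower. The chondrocyte list at 24 h turned from a relative median of -0.37 to 0.20 with the stricter filter, where 5 genes were left. Without multi-transcript probe sets the immediate early list at 24 h turned from 0.35 to -0.0562 and GINS2 from 3.04 to -0.0094, and the cause was not tested. Medians nearer 0 that changed sign under at least 1 setting were those of the destruction complex, osteoblast, chondrocyte, stromal surface, haematopoietic and endothelial lists at 6 h, and of the Wnt ligand, destruction complex, osteoblast, Notch and NF-kappaB lists at 24 h. Of 129 named genes past 2-fold at 24 h, 128 had a value with the 75th percentile and 113 of them stayed past it, and at 6 h 78 of 82 did. Signal over background limits genes near the filter level of 25.9, and the filter on the mean of 3 arrays can leave out genes bright on 1 array.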

Other observations

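The tests of epithelial markers, and the 3 further gene lists, were chosen after the results were seen.

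Of 16 measured keratin and keratin-associated genes besides KRT14, 8 were 2-fold higher and 1 lower at 6 h, against 1.98% of all genes higher, and 7 were higher and none lower at 24 h. KRT23 was at 1.36 and 0.83 and the pseudogene KRT8P12 at -1.03 and -0.57. KRT16 changed by 4.83, to a signal of 353 from a dim 5.01, so that size depends on the pseudocount. KRT7, a simple epithelial keratin, had signals of 218, 559 and 1537 on the control, 6 h and 24 h arrays, KRTAP1-1 of 216, 1331 and 2122, and KRTAP1-5 changed by 2.16 and 2.22. KRT33A, a hair keratin, changed by 1.45 and 2.62 and KRT9 by 1.39 and 1.82. KRT8 was at -0.76 and -0.20, KRTAP10-11 at -0.33 and -0.41 and KRTAP8-1 at 0.51 and -0.14. These genes were singled out after their values were seen, and KRTAP1 and KRT33 genes are near-identical, so their probe sets can share signal.

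Of 12 hypoxia and glycolysis genes 1 fell at 6 h and 2 at 24 h, ADM at -1.71 and -1.46 and HK2 at -1.17 at 24 h (at 24 h 1 rose and 1 fell with the other scalings; relative medians 0.29 and 0.17, percentiles 99.7 and 88.3). None of 7 heat shock and oxidative stress genes passed 2-fold, though 1 did at 6 h with the 75th percentile or the hybridization controls (relative medians 0.14 and 0.21, percentiles 77.3 and 81.7).

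KRT14 rose at 24 h to a signal of 1197. Epithelial cells in the sample stay open: of the 7 other epithelial markers 1, KRT19, was above the filter level and 2-fold above control at 24 h, at 55.3, and CDH1, from 4.78 to 25.4, missed that count by lying just under the filter level. Whether keratin genes rose together also stays open: 43.8% of the other measured KRT and KRTAP genes were 2-fold higher at 24 h, against 3.72% of all genes, but 3 of the 7 are KRTAP1 genes that can share signal, the 16 include pseudogenes and an antisense RNA, and KRTAP1-3 had been named before the count. Signal from a related keratin stays open too. Of those searched, 0 were 2-fold higher at a signal above KRT14's, but only KRT16 was searched, KRT17 was not analysed here, and signals of different probe sets cannot be set against each other.

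The lower cholesterol and interferon lists were followed in further genes. A wider fall of SREBP targets may go with the cholesterol list: 18 further targets had a relative median of -0.33 at 24 h, at percentile 0.45. Of these 5 were lower and none higher: SREBF1 (-2.35), LPIN1 (-2.25), FADS2 (-1.54), ACACA (-1.53) and ELOVL6 (-1.21). The sterol synthesis enzymes among the 18 stayed short of 2-fold: MVK (-0.55), PMVK (-0.45), MVD (-0.56), EBP (-0.03), NSDHL (-0.43) and HSD17B7 (-0.52). SREBF1 and LPIN1 were already at -1.24 and -1.09 at 6 h, when no gene of the cholesterol list had passed 2-fold. Of 17 further interferon-stimulated genes 5 were lower and none higher at 24 h. Their relative median was -0.25, at percentile 5.34, which lies between the bounds set for and against a wider fall and leaves it open.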
